A study of Bacillus methanolicus with 6 samples.

How the data were processed

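Total RNA of Bacillus methanolicus MGA3 was measured on 6 one-colour custom Agilent arrays, 3 of cultures grown on methanol and 3 of cultures grown on mannitol. Per the labels' protocols, RNA was preserved in RNAlater, extracted with a column kit and copied into cDNA that was coupled to Cy3. The deposited scanner tables give the intensity of each spot before and after background subtraction, with flags for spots well above background, saturated or outlying. Per the submitters' processing notes, they were made with Agilent Feature Extraction 9.5.1.1. The series' deposited value table holds the processed intensity of the same arrays, with a largest difference of 0 from the scanner tables. It is therefore on a linear scale, not centred and not scaled between arrays; its column medians were 5789, 6209 and 7749 for methanol replicates 1 to 3 and 5718, 5825 and 4802 for mannitol replicates 1 to 3.

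Each array holds 43803 gene spots and 1417 control spots, with 18480 probes of 45 to 60 bases, 5 for each of 3696 genes, spotted 2 or 3 times. The files name genes by identifier only, 3694 of them with a number from 1 to 3721 and 2 with another form. They pair no identifier with a gene name, and the genome assembly behind the probes is not given in the sources used here, so genes are named by identifier, no position is stated, and at most 2 genes that rose and 2 that fell are named. The 26 gene lists drawn up for pathways such as methanol oxidation and mannitol uptake matched 0 genes, and no list was tested.

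Control spots and outlier-flagged spots (0.845% to 0.963% of the gene spots per array) were left out. The log2 processed intensity was averaged over the spots of a probe after subtracting the array's 75th percentile over gene spots, which corresponded to intensities of 16400 to 25770. A gene's value on an array was the median over its 5 probes. A gene entered the test when at least 1 of its probes was well above background on at least 3 of the 6 arrays, a probe counting as such when at least 0.5 of its spots were; 43 genes did not. Saturated spots were kept. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 3653 tested genes and a threshold of 0.05. Positive log2 changes mean higher on methanol. For a gene not well above background on any array of a group, a bound is given: the mean of the bright group over the mean, in the dim group, of the higher of its own value and the lowest signal among probes well above background on that array.

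The steps from the median over probes to the calls were tested on simulated data with the real mean per gene. A gene's simulated spread was the same in both groups and was drawn by limma towards a value common to all genes. Genes with an unusual spread, or one that differs between the groups, were therefore not fully imitated. In the simulated data, 200 of 3653 genes were changed. Of these, 10% were called at a log2 change of 0.585, 66% at 1, 98% at 2 and 100% at 4. Among the 143 calls, 6 were genes that had not been changed. Spot removal, scaling and the filter on dim genes were not part of the simulation. Its noise was drawn independently for each gene, while on the real arrays many genes deviated together. These rates therefore need not hold for the real data.

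Samples were grouped by the carbon source in the labels. The labels speak of cultures on 3 different days, without saying that a replicate number marks a day, and the comparison was made without the number as a block. The design, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the genes with the largest rise and fall among those called whose groups did not overlap and which were well above background and not saturated on at least 1 array of each group, 10 in each direction; the first 2 in each direction are named and the rest are summarised. Genes with only a bound were to be listed separately, and are summarised as well. The probe sequences shown are those with the median change among a gene's 5 probes. Of the genes on the array, 17 share an identical probe with another gene, so that their values can mix; none of the 4 named genes is among them.

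Alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median, the deposited values without scaling, other filters on dim genes and probes, the mean over probes or the brightest probe in place of the median, eBayes with trend and robust settings, the replicate number or the slide as a block, slide 2 alone, and each array left out in turn. An alternative without the 17 genes that share probes was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.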

Results

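Bacillus methanolicus is a methylotrophic bacterium, one that can grow on methanol as its carbon source, and MGA3 is the strain studied. Transcript levels were measured in cultures of MGA3 grown in minimal medium on methanol (3 samples) or on mannitol, a sugar alcohol (3 samples), all harvested at an OD600 of 1. Per the labels, the cultures were grown in triplicate on 3 different days. Cy3-labelled cDNA of each sample was hybridised to 1 array, and each array carried 5 probes for each of 3696 genes. The gene spots were bright on all 6 arrays: 96.55% to 98.36% of them were well above background, and the median processed intensity ran from 5170 to 8385. Between 0 and 9 gene spots per array were saturated. Of the 3696 genes, 3653 entered the test. The number of arrays limits the precision of every value below.

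The comparison asked which genes are expressed differently in methylotrophic growth and in growth on mannitol. With 3 arrays per group, 722 of the 3653 genes (19.8%) changed in limma at an adjusted p under 0.05; 343 were higher on methanol and 379 were lower. Of these, 296 differed at least 2-fold, 141 of them higher and 155 lower. The genes at least 4-fold higher numbered 62 and those at least 4-fold lower 25; without mannitol replicate 2 these counts were 60 and 71, without mannitol replicate 3 they were 58 and 11, and without methanol replicate 3 they were 64 and 14. The genes that rose had a median log2 change of 0.873 and the genes that fell one of -0.867; both are medians over genes selected by the test. In each of the 722 genes, the 3 values of one group lay above the 3 of the other; that held for 44% of all tested genes, and chance gives 10%. Without adjustment, 1420 of the 3653 genes had a limma p under 0.05. An estimate from the distribution of these unadjusted p-values put 38.6% of the tested genes as unchanged, so the 722 need not be all genes that differ. The estimate does not allow for genes that deviate together on an array, so it is not a measured share. Over the alternatives, the number of genes with an unadjusted limma p under 0.05 ran from 993 without scaling to 1524 without mannitol replicate 2. The 5 probes of a gene moved in the same direction in 712 of the 722 genes (98.6%) and in 80.9% of the genes that were not called. The number of called genes fell by more than 1.5 times when 1 array was left out in 4 cases, to 474 without methanol replicate 1, 236 without methanol replicate 2, 192 without methanol replicate 3 and 337 without mannitol replicate 3. The 192 genes were 134 higher and 58 lower; at 2-fold or more, 113 genes were higher and 49 lower without methanol replicate 3, and 156 higher and 232 lower without mannitol replicate 2.

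**Figure D1:**
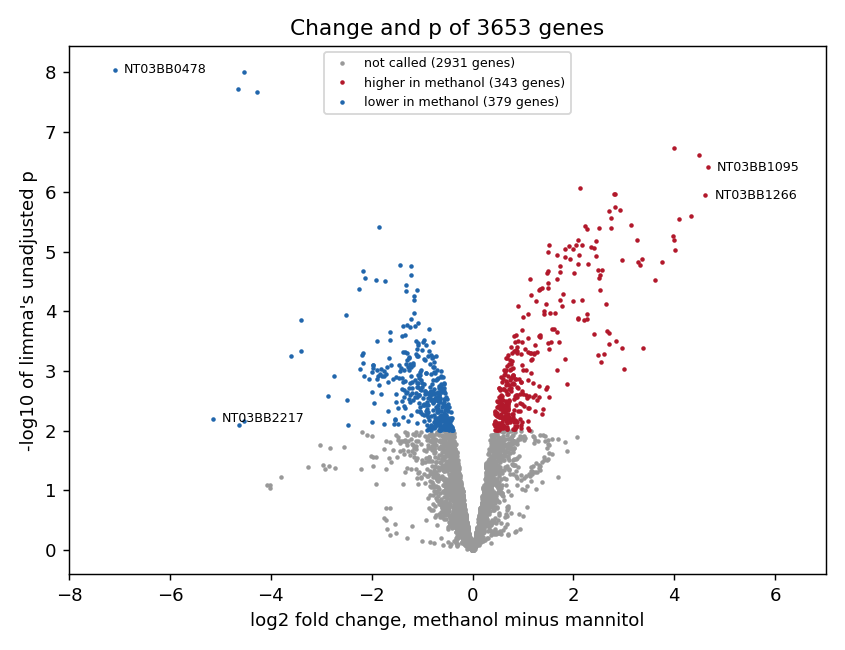
Each point is 1 of the 3653 tested genes; the horizontal axis is the log2 fold change of methanol over mannitol (3 arrays each), and the vertical axis is the negative log10 of limma's unadjusted p. The 343 genes higher on methanol are red, the 379 lower ones blue and the 2931 others grey; NT03BB0478 lies far to the left at -7.10, and NT03BB2217, at -5.14, lies much lower on the plot than NT03BB0478.

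The steepest rise belonged to NT03BB1095, which was 25.4-fold higher on methanol (log2 change 4.67, SE 0.225, limma adjusted p = 0.000202). Its level, as log2 intensity relative to the array's 75th percentile, was -1.06 ± 0.175 (SD, n = 3) on methanol and -5.73 ± 0.408 (SD, n = 3) on mannitol. The 5 probes of NT03BB1095 gave log2 changes between 4.64 and 4.74; the probe with the middle value, 4.69, has the sequence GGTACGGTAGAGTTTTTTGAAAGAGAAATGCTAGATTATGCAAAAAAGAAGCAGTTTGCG. NT03BB1266 followed with a 24.6-fold rise (log2 change 4.62, SE 0.264, limma adjusted p = 0.000377), from -4.71 ± 0.43 on mannitol to -0.09 ± 0.323 on methanol (SD, n = 3 each). Its probes disagreed: the middle one gave 4.49 and has the sequence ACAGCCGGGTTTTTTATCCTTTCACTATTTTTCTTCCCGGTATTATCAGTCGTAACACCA, while the brightest one gave only 0.088. Taken from that brightest probe alone, NT03BB1266 was not called (limma adjusted p = 0.759, with 1.52e-06 to 0.759 over its alternatives). The mean over its 5 probes gave 3.67, and the highest probe 4.81, so the brightest probe stood apart from the others. For both genes, all 3 methanol arrays lay above all 3 mannitol arrays. The 10 largest rises under the same rule ran from 3.76 to 4.67 on the log2 scale.

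The largest fall was that of NT03BB0478, which was 137-fold lower on methanol (log2 change -7.10, SE 0.191, limma adjusted p = 1.81e-05). Its level was 0.66 ± 0.118 on mannitol and -6.43 ± 0.337 on methanol (SD, n = 3 each), and it was well above background on all 6 arrays. The size of the fall of NT03BB0478 depended on the probe, from -2.56 for its brightest probe to -7.98; the middle probe, at -7.51, has the sequence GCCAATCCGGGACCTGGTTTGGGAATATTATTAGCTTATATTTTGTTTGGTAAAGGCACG. The mean over the 5 probes of NT03BB0478 gave -6.57, so its brightest probe stood apart from the others. NT03BB2217 was 35.3-fold lower on methanol (log2 change -5.14, SE 1.292, limma adjusted p = 0.0399). Its level was -4.0 ± 0.626 on methanol (SD, n = 3), and on mannitol it was 2.58, -2.04 and 2.89 in replicates 1, 2 and 3. Its 5 probes gave -5.23 to -4.92, and the middle one has the sequence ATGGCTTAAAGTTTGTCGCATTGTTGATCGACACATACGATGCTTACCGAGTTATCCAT. The call of NT03BB2217 was lost when methanol replicate 1, 2 or 3 or mannitol replicate 1 or 3 was left out (limma adjusted p = 0.0741, 0.107, 0.119, 0.0911 and 0.112; 0.00119 to 0.153 over its alternatives). It was also lost with the trend and robust settings of eBayes (limma adjusted p = 0.0613). Without mannitol replicate 2 its log2 change was -6.73. The 10 largest falls under the same rule ran from -7.10 to -3.39.

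**Figure D2:**
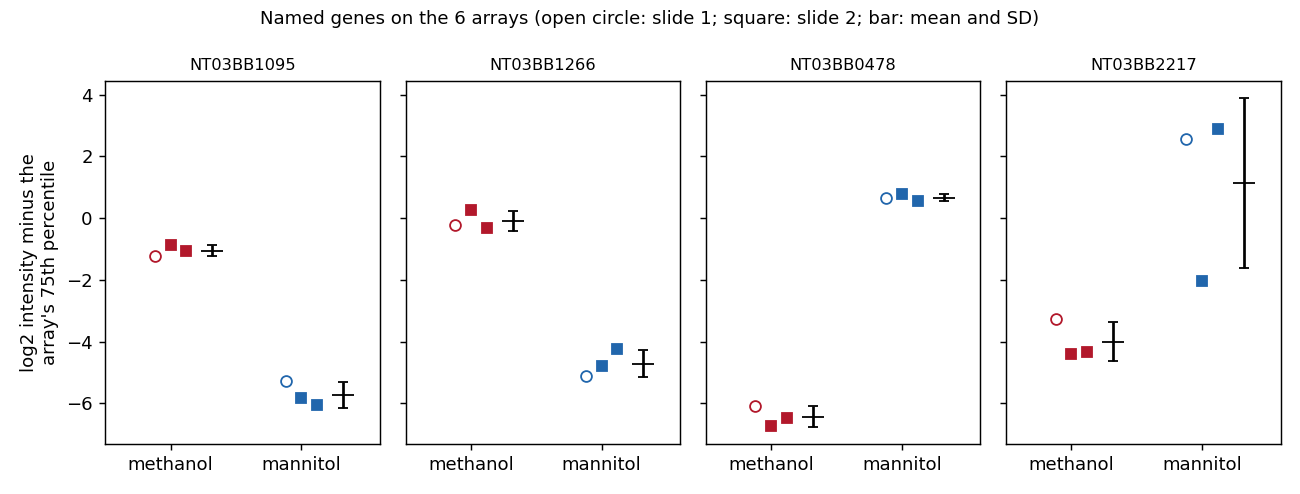
Levels of the 4 named genes on the 6 arrays, as log2 intensity minus the array's 75th percentile, with methanol in red and mannitol in blue; open circles are slide 1, squares slide 2, and the bars give the mean and SD of 3 arrays. The groups are far apart for NT03BB1095, NT03BB1266 and NT03BB0478, while mannitol replicate 2 of NT03BB2217, at -2.04, lies between the methanol arrays and the other mannitol arrays.

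**Figure D3:**
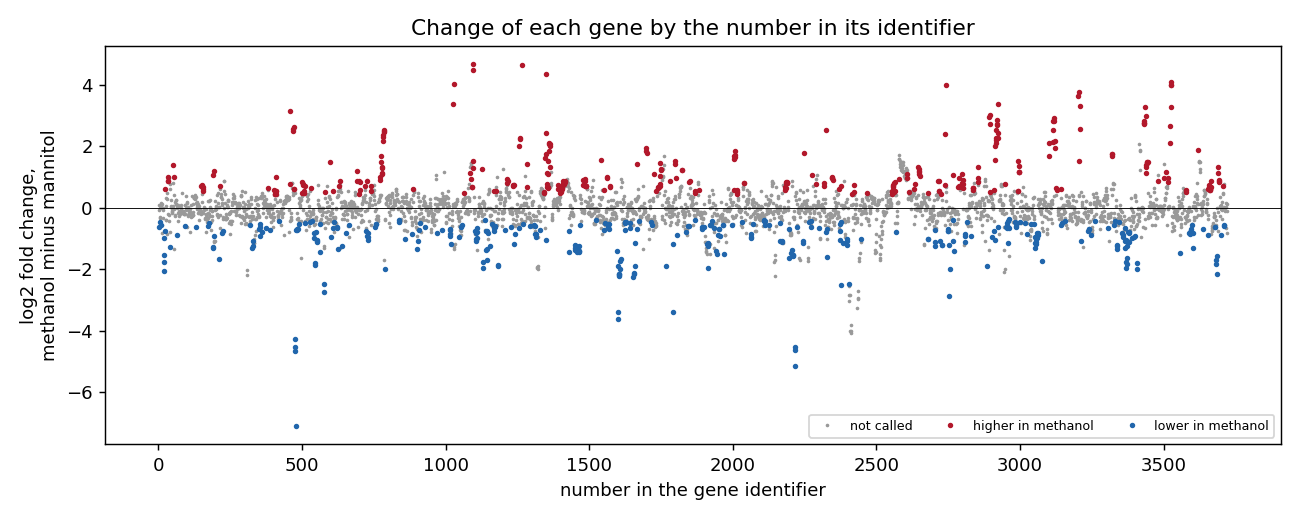
Log2 fold change of methanol over mannitol (3 arrays each) for every tested gene with a numbered identifier, against the number in the identifier; red genes were called higher on methanol, blue genes lower, and grey genes were not called. Called genes form vertical stacks of neighbouring numbers, among them the 4 genes that end with NT03BB0478, at -4.27 to -7.10.

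The arrays lay on 2 slides, with replicate 1 of both groups on slide 1 and replicates 2 and 3 on slide 2. With the slide as a block, 643 genes were called, 317 higher and 326 lower, and 595 of the 722 genes were among them. Within slide 2, with 2 arrays per group, limma called 282 genes, 157 higher and 125 lower. At 2-fold or more, 283 genes were called with the block and 257 within slide 2, against 296. Slide 1 holds 1 array per group and gives no test. All 722 genes had the same direction on slide 1 and on slide 2, as genes whose groups do not overlap must. NT03BB1095 was higher by 4.05 on slide 1 and by 4.97 on slide 2 (limma adjusted p = 0.0055 within slide 2 and 0.00188 with the slide as a block). NT03BB1266 was higher by 4.87 and 4.49 (adjusted p = 0.018 and 0.00198 in limma). For NT03BB0478 the log2 changes were -6.75 and -7.27 (adjusted p = 0.00431 and 0.00037 in limma). For NT03BB2217 they were -5.85 and -4.79, and its call was lost both within slide 2 and with the block (adjusted p = 0.153 and 0.0523 in limma).

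Arrays of the methanol group resembled each other most, with correlations across genes of 0.982 to 0.987; those within mannitol were 0.961 to 0.985, and those between the groups 0.927 to 0.959. The first principal component held 59.2% of the variance and separated the groups. The second held 20.9% and set mannitol replicate 2, at -28.1, apart from the other arrays, which lay between -6.45 and 15.7. In 52 genes the mannitol arrays lay at least 8-fold apart; mannitol replicate 2 was the one apart in 46 of them, and it was lower in all 46. Without mannitol replicate 2, 820 genes were called, 420 higher and 400 lower, and 579 of the 722 genes were among them. Of the 52 genes, 38 lay in 8 runs of consecutive identifier numbers.

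**Figure D4:**
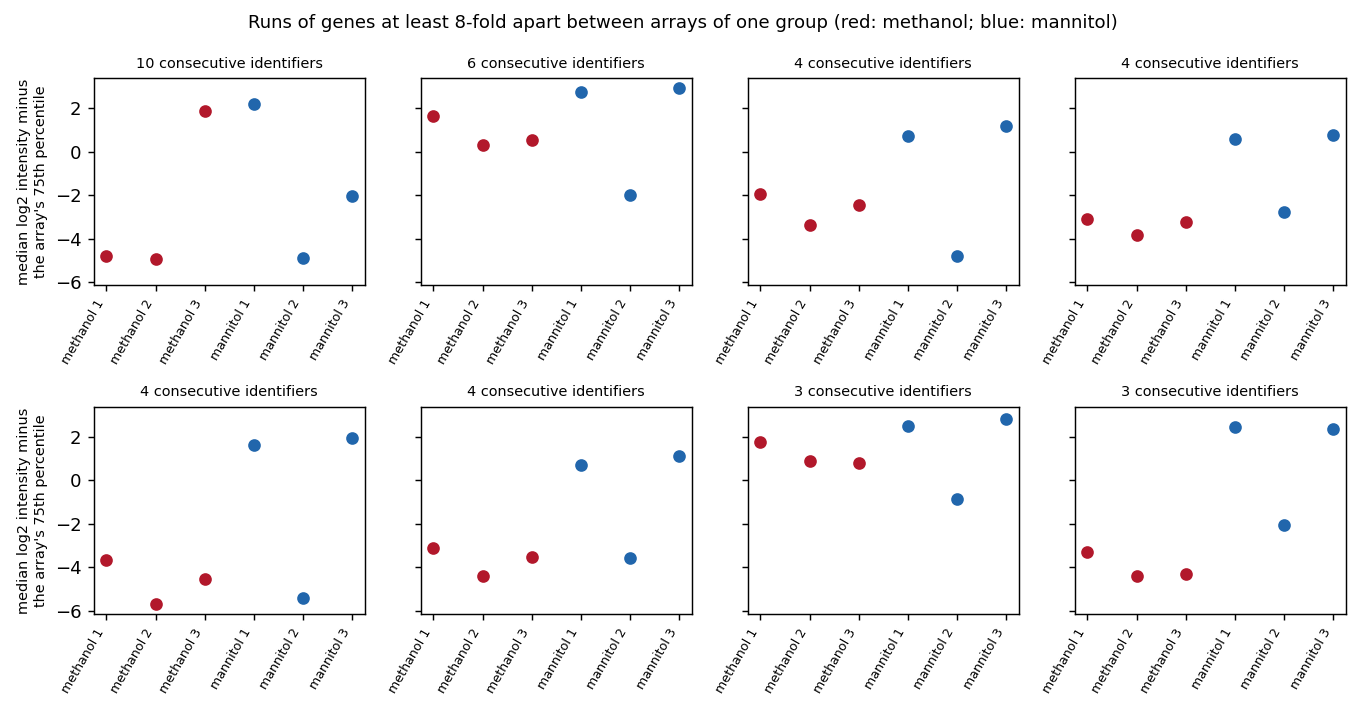
Median level of each of the 8 runs of consecutive identifiers at least 8-fold apart within a group, per array, as log2 intensity minus the array's 75th percentile; methanol arrays are red and mannitol arrays blue. In the run of 10 genes, methanol replicate 3 (1.85) and mannitol replicate 1 (2.18) are high. Mannitol replicate 2 is the lowest mannitol array in that run (-4.91) and in the other 7 runs.

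The balance of rises and falls also varied with the scaling: the 722 genes split into 343 and 379, while centring on the median gave 258 higher and 558 lower genes and the deposited intensities without scaling gave 278 higher and 172 lower. Of the genes changed at least 2-fold, 47.6% were higher; the share was 61.4% without scaling (216 higher, 136 lower) and 39% with centring on the median (134 higher, 210 lower). Of the 2931 genes not called, 2225 had a 95% confidence interval that lay inside a 2-fold change in either direction, and 142 had a log2 change of at least 1 in size. Among genes near the background, 4 were not well above background on any of the methanol arrays but were on all 3 mannitol arrays. Of these, 1 was called, at least 1.3-fold higher on mannitol (limma adjusted p = 0.0207, all 3 mannitol arrays above all 3 methanol arrays); the other 3 had bounds of 1.2-fold to 1.35-fold and were not called (limma adjusted p = 0.127 to 0.291). There was no gene with the opposite pattern.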

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

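Among the control spots, which the comparison does not use, 25 of 59 control probes, the bright corner marks left out, were well above background on all 6 arrays. The brightest, ETG10_234183, was 214 to 356 times as bright as the negative controls of the same array, and was singled out because it gave a signal in data outside the main measurement; the second brightest by its lowest array was at 15.6 times. What the probe is meant to detect is not given in the sources used here, and no explanation was tested. The rule for a sample far from the others of its group needs groups of at least 4, so it could not be used on groups of 3.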

How the results depend on the processing

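The alternative without genes that share an identical probe was chosen after the result was seen. Each count was recomputed under 20 alternatives, and 31 values lay within 1.5 times the reported count and 9 beyond. Against 722 genes, limma called 450 from the deposited intensities without scaling, where the median change of all genes moved by 0.174 (log2), 282 within slide 2 alone, and 216 with the replicate number as a block; for changes of at least 2-fold, the block gave 165 against 296. Leaving out 1 array at a time gave 192 to 820 genes, and 162 to 388 genes at 2-fold, with the lowest count without methanol replicate 3 and the highest without mannitol replicate 2. Fewer arrays enter the tests within slide 2 and without an array. That alone does not account for the rise to 820 and 388 without mannitol replicate 2. The rise does not show how much of the falls comes from having fewer arrays. The causes were not tested for any of the alternatives. The replicate numbers were not used as pairs, and whether they mark a shared day stays open. The deviations of same-numbered arrays from their group means correlated across genes at -0.0097, 0.4 and -0.19. Only 2 of the 6 arrays, methanol and mannitol replicate 2, correlated best with their own number. The highest correlation between the groups was 0.54, for methanol replicate 3 with mannitol replicate 1. The lowest was -0.62, for methanol replicate 2 with mannitol replicate 1. With the block, 143 genes were higher and 73 lower, and 208 of the 722 genes were called. None of the 722 genes changed direction under the alternatives, except 1 with the mean over probes and 9 with the brightest probe. For many alternatives this was fixed in advance. Genes whose groups do not overlap keep their direction within slide 2 and without an array. The blocks, the eBayes settings and the filters on genes leave the change itself as it was. Centring on the median and leaving out the scaling moved the change of every gene by the same amount, -0.0935 and 0.174 (log2). They could reverse only a gene with a smaller change than that. Only the other background correction, quantile normalization and the other choices of probes could reverse a gene with a larger change. NT03BB1095 and NT03BB0478 kept their call under all 20 alternatives, with log2 changes of 4.42 to 4.97 and -7.27 to -2.56; NT03BB1266 kept it under 19 and NT03BB2217 under 11, from -6.73 to -4.27; with the replicate block its limma adjusted p was 0.0582 (0.00119 to 0.153 over its alternatives). The gene lists matched no gene, so none of the alternatives for list tests was run. Of the 3696 genes, 3622 were above background on each of the 6 arrays and 17 on none, so signal over background limited few genes.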

Other observations

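The tests of wrong labelling, of slides, of probe GC content and of genome order, the shuffles and the choice of the runs described here were made only after the results were seen. Changed genes with consecutive identifier numbers tended to lie together: 373 of the 722 genes (51.7%) fell into 71 runs of at least 3 consecutive numbers that changed in the same direction, 36 runs higher and 35 lower on methanol. When the calls were shuffled over the identifiers 1000 times, a median of 18 and at most 56 genes fell into such runs. The longest run held 17 genes, all lower on methanol, with log2 changes of -1.45 to -1.22, against a longest of 7 in the shuffles. The run of 4 genes that ends with NT03BB0478 fell, with log2 changes of -7.10 to -4.27 (limma adjusted p at most 2e-05), and in each of the 4 genes all 3 methanol arrays lay below all 3 mannitol arrays. The run of 4 genes that holds NT03BB1095 was higher by 1.29 to 4.67 (limma adjusted p at most 0.011). A run of 5 genes had the highest median rise, 3.97, and 12-gene runs rose by medians of 1.92 and 2.34. In all, 9 runs were higher and 4 lower with a median change of at least 4-fold. The 3-gene run that ends with NT03BB2217, with log2 changes of -5.14 to -4.53, is among the 4 and rests on mannitol arrays that lie far apart.

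The first pattern weighed is the set of 722 changed genes itself. The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05; 1 of the 10 splits, the real one, gave 722 genes, and the highest of the others gave 2. A trend with the GC content of the probes could give calls without any change of the transcripts, but it was small: for 4.7% of the 722 genes (34) it had the sign of the change and at least 0.5 of its size, which argues against it as the whole cause. Removing the trend from every array moved values by a median of only 0.019 (log2) and left 628 of the 722 genes called, so that removal decides little by itself. Carbon source, the difference that the design names, stays open as the explanation, as do other differences between cultures that went with it.

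The second pattern is that genes with consecutive numbers change by similar amounts, with r = 0.63 across 3591 pairs (genes are not independent replicates; permutation p = 1e-04, the smallest that 10000 shuffles can give). A trend with probe GC content held 0.93% of the variance of the change, too little for such a correlation. Only 8 pairs had probes that share 15 bases, and r was 0.627 without them, which argues against cross-hybridisation through stretches of that length. Touching spots of genes over 20 numbers apart had changes that correlated at -8.8e-05, which argues against the position on the glass; the correlation between genes fell to 0.45, 0.34, 0.23 and 0.074 for numbers 2, 3, 5 and 10 apart, so that consecutive numbers stood 0.554 above numbers 10 apart. As a hypothesis, the identifiers may follow the order of the genes on the genome and neighbours may be transcribed together; no genome was used here to test that further.

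The third pattern is that runs of genes lay far apart between arrays of one group. Of the 52 genes at least 8-fold apart within mannitol, 38 fell into 8 runs of at least 3 consecutive numbers. At most 3 genes did so in 1000 shuffles. Only 3 of the 52 were among the 722, but genes chosen for a wide spread within a group are hard to call. Without mannitol replicate 2, 31 of the 46 genes in which that array stood apart were called. That fit leaves out the array that made the spread, so neither count decides whether these genes follow the carbon source. In 96.2% of the 52 genes (50), all 5 probes differed at least 2-fold in the same direction. The 52 genes were chosen by the median over 5 probes, so a fault on the glass in single probes could hardly bring a gene into the set. The choice thus favoured this high share, which decides little about such a fault. Of the 52 genes, 86.5% (45) were at least 8-fold apart between mannitol replicates 2 and 3, which share a slide. A difference between slides is therefore not the cause for most of them. Genes at least 4-fold higher on methanol in the fit without mannitol replicate 2 (60) argue against a methanol sample under that label and against methanol-culture RNA mixed into it: on a scale from 0, the mean of the other mannitol arrays, to 1, the methanol mean, their median in mannitol replicate 2 was 0.041 (quartiles -0.07 and 0.14), and 0 of the 60 genes (0%) lay nearer to methanol. The 71 genes at least 4-fold lower on methanol in that fit had a median of 0.73 (quartiles 0.13 and 0.97) on the same scale, so mannitol replicate 2 resembled methanol for many of those genes; the day of culture, which per the labels differs within a group, was not tested as an explanation.

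The run of 10 genes from NT03BB2511 to NT03BB2520, chosen after its values were seen, did not follow the carbon source. Its median level was 1.85 in methanol replicate 3 and 2.18 in mannitol replicate 1, against -4.81 and -4.94 in methanol replicates 1 and 2, -4.91 in mannitol replicate 2 and -2.04 in mannitol replicate 3. These 10 genes were the only ones at least 8-fold apart within methanol, and none of them was among the 722. In the other 7 runs mannitol replicate 2 was again the lowest mannitol array. In 3 of these, of 6, 4 and 3 genes, it also lay below every methanol array. Its medians there were -2.02, -4.81 and -0.86, against lowest methanol medians of 0.29, -3.37 and 0.80. By these medians, methanol replicate 2 was the lowest methanol array in the 7 runs, except in the 3-gene run with 0.80, where it was at 0.91. In the run that ends with NT03BB2217 its median was only slightly below that of methanol replicate 3 (-4.396 against -4.325). The other genes of that run were lower in methanol replicate 3. The methanol arrays lay less far apart, with median ranges of 0.74 to 2.02 (log2) in the 7 runs against 3.56 to 7.39 in mannitol. Whether this shared pattern goes with the day of culture was not tested.

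On the scale used for mannitol replicate 2, earlier forms of the test of wrong labelling had given medians of -0.06 for the 4-gene run that ends with NT03BB0478 and 0.14 for all 131 genes at least 4-fold apart in either direction. They were replaced after these values were seen, because genes higher and lower on methanol lay at different places on the scale.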
